A study of Mus musculus with 8 samples.

How the data were processed

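RNA was measured in CD4 T cells sorted from the mesenteric lymph nodes of mice that carried reporter alleles at Foxp3, the gene of the transcription factor that defines regulatory T (Treg) cells. Per the labels, 1 Foxp3 reporter expressed the diphtheria toxin receptor with GFP and the other carried Thy1.1, and a tamoxifen-activated Cre under CD4 control switched on the red protein tdTomato. The labels do not say what the Thy1.1 allele does beyond marking cells. PolyA RNA was amplified with the SMART-Seq v4 kit in 12 cycles, 2 to 10 ng of cDNA entered a KAPA Hyper Prep library with 8 PCR cycles, and 50-nt paired ends were read, per the labels' protocols. This kit does not mark strand, so reads of overlapping or antisense genes cannot be assigned to 1 of them.

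The authors deposited raw read counts per gene in 1 table, as whole numbers with no normalization, per the file headers and the values. The aligner, the counter, the annotation and the genome build are not given in the sources used here. The submitters' processing notes name DESeq with no version. The table held 24116 rows, of which 8 had no gene name. Those held 0.0215% to 0.0264% of the counts of a library and were left out of the tests and of the totals used for scaling. Of the 24108 named genes, 23400 (97.06%) had a symbol in the GENCODE annotation used here, which served only to find overlapping exons and chromosomes.

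Each of 4 populations (tdTomato-negative or tdTomato-positive, GFP or Thy1.1) had 2 libraries. The table numbers the Thy1.1 libraries 1 and 2, as the sample titles do, and the GFP libraries 3 and 4, where the titles say 1 and 2. The GFP columns were therefore matched to their population only and are named here by the numbers in the table. Library totals, unnamed rows included, lay between 38085686 and 47908198 counts. CPM is the count scaled to a common library total. Over named genes alone, 3 counts, the limit that a count of 0 allows, corresponded to 0.0626 to 0.0788 CPM. The labels do not say that the 2 libraries of a population came from separate animals, so p-values measure the spread between these libraries, which may be technical. Intervals for low counts and limits from a count of 0 cover counting error only, at 95% confidence.

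Tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by edgeR's expression filter with a minimum count of 10, which left 13989. Libraries were scaled by TMM, with factors from 0.978 to 1.02, and 1 quasi-likelihood model with robust dispersion was fitted to all 8 libraries with a mean per population. It left 4 residual degrees of freedom and had a common biological coefficient of variation of 0.399. The 5 tests were GFP against Thy1.1 within tdTomato-positive cells and within tdTomato-negative cells, tdTomato-positive against tdTomato-negative within each reporter, and the interaction of the label with the reporter. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic.

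The groups, tests, named alternatives, 27 gene lists and the rule for named genes were fixed before the data were examined. The lists covered Treg and helper T cell programmes, naive, thymocyte and gut homing genes, cell cycle, receptor and stress responses, metabolism, and markers of other cell types. Several lists share members, so calls of such lists partly repeat the same genes. There were 27 lists in all. Of these, 26 had at least 3 tested members and were tested against all other genes with camera at a preset correlation of 0.01. An estimated correlation and fry were alternatives. Fry's directional p asks whether the genes of a list move on balance 1 way and does not compare the list with other genes. The rule named, per comparison, the 10 genes with the largest change in each direction among those past the threshold with a mean of at least 5 CPM and no overlap between the 2 populations, leaving out unnamed gene models and antigen receptor segments, up to 4 members of each list with the smallest adjusted p, and 12 genes in every comparison whatever their values. Results of some genes, 2 of the 12 among them, are not reported here, and counts over lists include them while counts of named genes do not. Thy1 in tdTomato-positive cells, Slc7a10 and Klrg1 outside their rule's comparisons, single gene values taken from other comparisons, and the gene families of the closing part were chosen after their values were seen.

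The pipeline was tested on simulated data with 50 genes changed at each of 4 fold sizes. For GFP against Thy1.1 in tdTomato-positive cells, over 13724 simulated genes, it recovered 76% of genes lowered to 0.25 of their level, 38% of those lowered to 0.5, 34% of those raised 2-fold and 78% of those raised 4-fold, with 5 false calls. For the tdTomato label within Thy1.1 cells, where no change was simulated, it made 0 calls. Alternatives were size factors by the RLE method, library totals alone, no filter, a filter of 5 CPM in 2 libraries, limma-voom, DESeq2, a fit to the 2 populations compared, a block for the replicate number, and each library left out in turn. A block of odd against even column numbers, leaving out both GFP libraries numbered 3 and thinning to 1 total were added after the data were seen.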

Results

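The study followed Foxp3-expressing CD4 T cells in mesenteric lymph nodes after microbial colonization. Mice were raised with AVNM, which the labels do not spell out, and a diet defined in its amino acids, and tamoxifen then marked CD4 T cells with tdTomato during about 3 weeks in which diphtheria toxin was also given. Per the design text the mark falls on cells outside the thymus that lack Foxp3. A marked cell that expresses Foxp3 later is therefore a candidate peripherally induced Treg cell. The labels name the toxin receptor with the GFP reporter only, so Foxp3-expressing cells of the Thy1.1 reporter may have escaped the toxin. Marked Thy1.1 cells may thus include cells that already expressed Foxp3 when marked, which was not tested. Cells were sorted 12 days after a change to chow and colonization with a fecal microbiota. The 4 populations were tdTomato-negative and tdTomato-positive cells with the GFP or the Thy1.1 reporter of Foxp3, with 2 libraries each.

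Library totals, unnamed rows included, were 47105591 and 43171231 counts in tdTomato-negative Thy1.1 cells, 47908198 and 42702010 in tdTomato-positive Thy1.1 cells, 45764437 and 46007968 in tdTomato-negative GFP cells, and 45074415 and 38085686 in tdTomato-positive GFP cells. Between 14943 and 15863 genes had a count. Across genes, the log2 CPM of the 2 libraries of a population correlated with r from 0.935 in tdTomato-positive GFP cells to 0.966 in tdTomato-positive Thy1.1 cells, and each pair differed by far more than counting noise (chi-square per degree of freedom from 38.3 to 82.9). The first principal component held 34.58% of the variance. It placed both tdTomato-positive GFP libraries at 96.9 and 98.4, both Thy1.1 populations between -56.3 and -36.1, and the tdTomato-negative GFP libraries at 6.85 and -18.4.

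**Figure D1:**
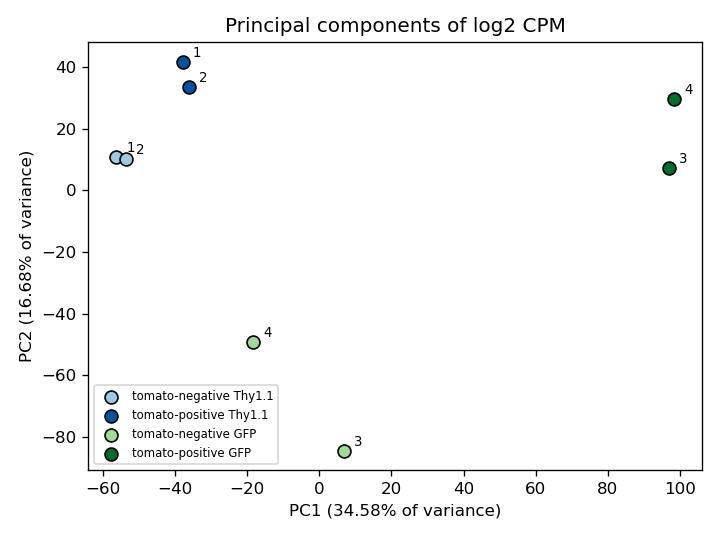
Principal components 1 and 2 of log2 CPM for the 8 libraries, with the share of variance on each axis, coloured by population and marked with the column number. The tdTomato-positive GFP libraries lay apart on component 1 (96.9 and 98.4).

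Foxp3 and Thy1 served as a check of the sort. Foxp3 was present in all 8 libraries, from 126 to 201 CPM, with 175 and 201 CPM in tdTomato-negative Thy1.1 cells and 126 and 141 CPM in tdTomato-positive GFP cells. Exons of Foxp3 overlap those of Ccdc22, and the alleles are engineered, so its level is uncertain. Thy1, the gene of the Thy1.1 antigen, lay at 72.6 to 93.2 CPM in the 4 Thy1.1 libraries and at 36.3 to 51.6 CPM in the 4 GFP libraries.

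Markers of other cell types were uneven between libraries. The tdTomato-negative GFP library 3 held 34.0 CPM of H2-Aa, an MHC class II gene, and 36.8 CPM of Siglech, a plasmacytoid dendritic cell gene, whereas no other library exceeded 1.31 and 1.19 CPM. Lyz2, a myeloid gene, reached 20.4 CPM in that library and 21.9 CPM in tdTomato-positive GFP library 3. The latter also held 29.5 CPM of the haemoglobin gene Hba-a2, against 3.55 CPM in tdTomato-positive GFP library 4. Cd74, an antigen presentation gene, lay at 32.9 to 92.5 CPM in 7 libraries and at 174 CPM in tdTomato-negative GFP library 3. Cd8a was 7.16 and 6.96 CPM in tdTomato-negative Thy1.1 cells and 0.542 and 0 CPM in tdTomato-positive GFP cells, whereas Cd8b1 lay between 6.68 and 25.7 CPM in all 8 libraries.

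The central comparison asked how marked Foxp3-expressing cells differed by reporter, GFP against Thy1.1. The labels do not say whether cells of the 2 reporters came from the same animals. A difference of source or preparation thus cannot be told apart from the reporter. In tdTomato-positive cells, genes tied to thymic origin of Treg cells were lower with GFP, and genes of the intestinal Treg programme were higher. Ikzf2, which encodes Helios, fell by 2.34 ± 0.25 (SE of log2, 2 libraries per population; edgeR adjusted p = 0.00193), from 728 and 847 CPM to 183 and 128 CPM. Nrp1, a surface receptor of thymic Treg cells, fell by 2.45 ± 0.17 (edgeR adjusted p = 0.000626), and Swap70 fell by 3.69 ± 0.25. The transcription factor gene Maf rose by 1.83 ± 0.25 (edgeR adjusted p = 0.00417). The cytokine gene Il10 rose by 2.36 ± 0.43 (edgeR adjusted p = 0.0112), and Foxp3 itself fell by 0.48 ± 0.12 (edgeR adjusted p = 0.0314).

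The lists gave these changes as groups. Of 10 thymic Treg-associated genes, 0 rose and 9 fell, 9 also when adjusted over the list alone, with a median log2 fold change of -2.32 (camera adjusted p = 3.466e-20; adjusted p = 0.0569 with an estimated correlation). Plagl1 was lower at -5.72 ± 0.80 and Cd83 at -1.52 ± 0.11. Of 17 intestinal Treg genes, 14 rose and 0 fell, 15 rose when adjusted over the list alone, and the median was 1.83 (camera adjusted p = 7.027e-24; adjusted p = 0.0673 with an estimated correlation). Ahr, the aryl hydrocarbon receptor, rose by 1.75 ± 0.16, Icos by 1.76 ± 0.19, Prdm1 by 2.15 ± 0.17 and Lag3 by 2.55 ± 0.22. Of 14 Th17 genes, 7 rose and 0 fell (8 rose when adjusted over the list alone), among them the interleukin-1 receptor gene Il1r1 with 3.58 ± 0.41 (camera adjusted p = 6.041e-09; adjusted p = 0.11 with an estimated correlation). Of 17 suppressor effector genes, 9 rose and 3 fell (10 and 3 when adjusted over the list alone), with Ctla4 up by 1.39 ± 0.15, Nt5e up by 0.73 ± 0.08 and Ebi3 down at -1.84 ± 0.23 (camera adjusted p = 2.422e-07; adjusted p = 0.103 with an estimated correlation). Exons of Ebi3 overlap a gene model, so its level is uncertain.

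Of 50 cell cycle genes, 49 rose and 0 fell, also when adjusted over the list alone, with a median of 2.56 (camera adjusted p = 2.498e-56; adjusted p = 0.0569 with an estimated correlation). Stmn1 rose by 3.44 ± 0.28, the replication licensing gene Mcm2 by 1.27 ± 0.11, the cyclin gene Ccna2, which overlaps Exosc9, by 2.60 ± 0.22, and Mki67 by 2.48 ± 0.40 (edgeR adjusted p = 0.00722). Of 19 naive and lymphoid homing genes, 0 rose and 13 fell (15 when adjusted over the list alone), with a median of -0.81 (camera adjusted p = 1.621e-22; adjusted p = 0.0569 with an estimated correlation). Ccr7 fell by 0.93 ± 0.12 (edgeR adjusted p = 0.00374), with Bcl2 at -2.51 ± 0.18, Id3 at -2.37 ± 0.14 and Bach2, which overlaps an antisense gene, at -1.32 ± 0.12. Of 14 gut homing genes, 8 rose and 1 fell (9 and 2 when adjusted over the list alone), including the chemokine receptor gene Ccr2 with 2.64 ± 0.23 and the colon homing receptor gene Gpr15 with 1.68 ± 0.19 (camera adjusted p = 7.377e-06; adjusted p = 0.152 with an estimated correlation).

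Of 16 GATA3 tissue Treg genes, 8 rose and 1 fell (9 and 1 when adjusted over the list alone; camera adjusted p = 5.064e-05; adjusted p = 0.0673 with an estimated correlation). Ccr4 rose by 2.36 ± 0.25 and Gata1 fell by 3.77 ± 0.30, whereas Gata3 was at 0.53 ± 0.23 (edgeR adjusted p = 0.171) and Il1rl1, which encodes the interleukin-33 receptor ST2, at -0.54 ± 0.33 (edgeR adjusted p = 0.321). Glycolysis genes rose in 10 of 20 cases and fell in 1 (11 and 1 when adjusted over the list alone; camera adjusted p = 1.293e-05; adjusted p = 0.11 with an estimated correlation), with Ldha at 1.02 ± 0.10 and Pkm at 0.91 ± 0.10. Cholesterol synthesis genes rose in 12 of 24 cases and fell in 0 (13 and 1 when adjusted over the list alone; camera adjusted p = 3.129e-06; adjusted p = 0.191 with an estimated correlation), with Fdps at 1.16 ± 0.15. Of 12 thymocyte and recent emigrant genes, 1 rose and 4 fell, as when adjusted over the list alone (camera adjusted p = 0.000274; adjusted p = 0.114 with an estimated correlation), with Satb1 at -0.96 ± 0.10 and Ldhb at -2.41 ± 0.18. Of 18 NF-kB response genes, 0 rose and 4 fell (1 and 6 when adjusted over the list alone; camera adjusted p = 0.00401; adjusted p = 0.138 with an estimated correlation), with Rel at -1.69 ± 0.23.

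The other lists were not called by camera in this comparison. Their adjusted p was 0.161 for 20 Treg core genes, of which 6 rose and 7 fell (6 and 9 when adjusted over the list alone), 0.631 for Th1, 0.065 for both Th2 and Tfh, 0.106 for both T cell receptor signalling and handling stress, 0.631 for interferon response and 0.228 for TGF-beta and retinoid response. Th2 genes rose in 2 of 10 cases, among them Il4 with 1.88 ± 0.36, and Tbx21, which encodes the Th1 factor T-bet, was at 0.97 ± 0.32 (edgeR adjusted p = 0.0853). Handling stress genes rose in 3 of 20 cases and interferon genes in 0 of 31 without a block for the column numbers. For marker lists of other cells the camera adjusted p was 0.0951 for B cell and for erythroid genes, 0.817 for plasma cell, 0.442 for CD8 and NK cell, 0.993 for myeloid and dendritic, and 0.688 for stromal and epithelial genes. The gamma-delta T cell list had 2 tested members, of which 1 rose, and was not tested as a list.

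The genes with the largest changes included several that were near 0 in 1 population. Slc7a10, an amino acid transporter gene, had 0 counts in tdTomato-positive GFP cells against 2066 with Thy1.1, at least 606-fold lower, and Noxa1 was at least 455-fold lower. Their exons overlap those of Lrp3 and Entpd8. Zc3h12c had 3 counts against 1008, a ratio of 296 (counting interval 101 to 1440). Ryr2 fell by 4.61 ± 0.45, with Sorcs2 at -4.38 ± 0.55, Lad1 at -4.84 ± 0.89, Nol4l at -4.45 ± 1.12, and the overlapping pair Arhgap20 and Arhgap20os at -4.75 ± 0.79 and -4.38 ± 0.84. On the other side, the mitotic kinase gene Pbk was at least 331-fold higher in GFP cells, and the replication gene Mcm10 had a ratio of 1129 (312 to 9330) and Hmmr of 686 (190 to 5670). E2f7 rose by 7.56 ± 0.98, Ccnb2 by 6.59 ± 0.80, Birc5 by 5.84 ± 0.51, Neil3 by 5.84 ± 1.29, Nqo1 by 6.21 ± 1.35 and Padi4 by 5.79 ± 1.23. Hba-a2 rose by 7.73 ± 1.65, with 29.5 CPM in GFP library 3 and 3.55 CPM in GFP library 4. Fitted sizes hinged on single libraries for 15 of the 55 named genes past the threshold, whose fold moved by over 1.5 times with 1 tdTomato-positive library left out. Without GFP library 3 and without GFP library 4 of these cells, Lad1 was at -13.05 and -3.91, Nol4l at -12.89 and -3.503, Arhgap20 at -7.907 and -3.896, Arhgap20os at -7.278 and -3.539, Plagl1 at -4.887 and -7.933, Zc3h12c at -11.95 and -7.298, and Hba-a2 at 5.455 and 8.549. Without GFP library 3, Sorcs2 was at -5.429, Ryr2 at -5.268, Ccnb2 at 5.673 and Nqo1 at 5.543. Without Thy1.1 library 1 and without Thy1.1 library 2, Neil3 was at 4.772 and 12.16, Nqo1 at 5.334 and 8.122, Mcm10 at 13.01 and 9.058, E2f7 at 6.939 and 8.37 and Ccnb2 at 5.966 and 7.436, and without Thy1.1 library 1 Mki67 was at 3.245 and Arhgap20os at -3.659. Values with a population at or near 0 counts, as for Mcm10 and Zc3h12c, depend on the prior count and give no size.

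In all, 1120 genes were higher and 954 lower in tdTomato-positive GFP cells (2074 of 13989; 4181 at an unadjusted p under 0.05). Which direction held more genes depended on the processing, with 886 higher and 1120 lower under library totals, 1109 and 1210 with the stricter filter, 1572 and 1592 by DESeq2 and 543 and 851 without tdTomato-positive GFP library 3. The count was 481 without Thy1.1 library 1 and 524 without Thy1.1 library 2 of the tdTomato-positive cells. Of the 55 named genes past the threshold, 43 kept their call with each of the 8 libraries left out. Calls were lost for Foxp3, Il4, Hba-a2, Noxa1 and Nqo1 without either tdTomato-positive Thy1.1 library or GFP library 3, for Il10, Hmmr, Lad1 and Padi4 without either of those Thy1.1 libraries, for Thy1 without Thy1.1 library 2, for Arhgap20os without Thy1.1 library 1, and for Nol4l without any of the 4 Thy1.1 libraries. Gata3 passed without GFP library 4 of the tdTomato-positive cells. Each of the 12 list calls held with any 1 library left out, and 0 held with an estimated correlation.

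**Figure D2:**
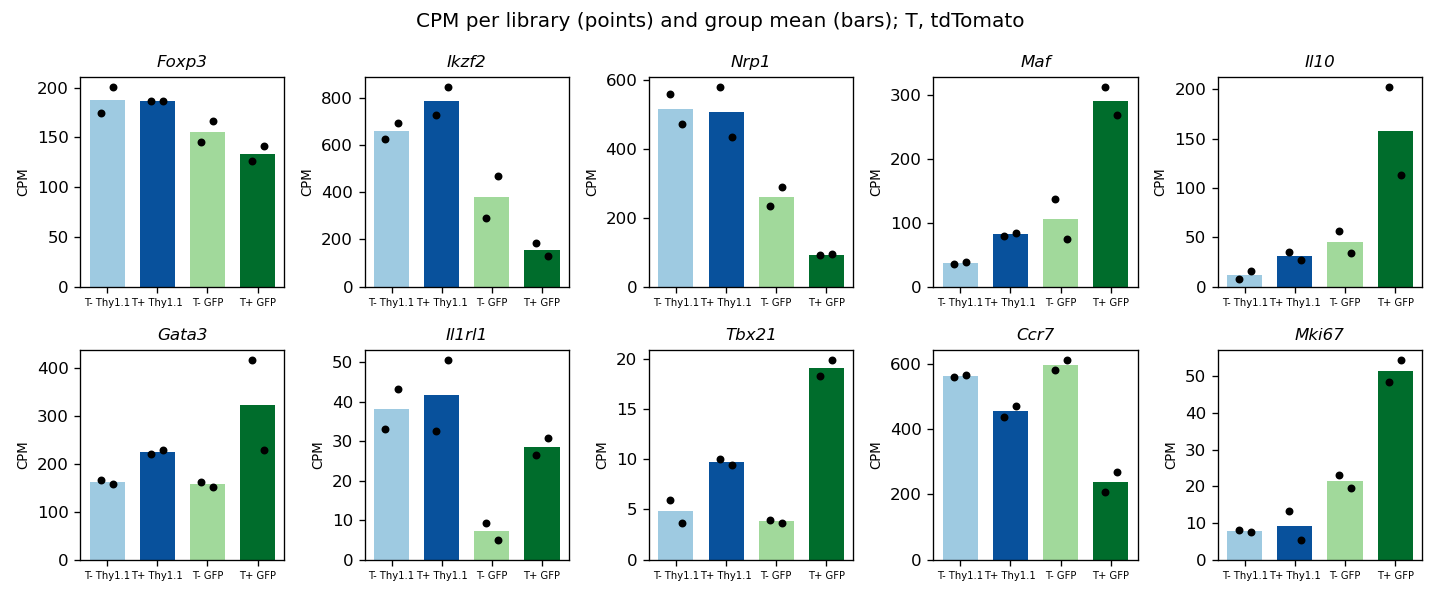
CPM of 10 genes named in every comparison, with 1 point per library and a bar for the mean of 2 libraries, in tdTomato-negative (T-) and tdTomato-positive (T+) cells of each reporter. Ikzf2 and Nrp1 were lowest and Maf and Il10 highest in tdTomato-positive GFP cells, at 183 and 128 CPM for Ikzf2.

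Within GFP cells, the comparison of marked and unmarked cells asked what set candidate peripherally induced cells apart from other cells with the same reporter. Toxin given during marking may have changed which unmarked GFP cells were present, so they need not represent an undisturbed Treg pool. This was not tested. Marked cells had less naive and thymic expression and more effector expression. Ccr7 fell by 1.32 ± 0.12 (SE of log2, 2 libraries per population; edgeR adjusted p = 0.00155). Ikzf2 fell by 1.29 ± 0.24 (edgeR adjusted p = 0.0156), and Nrp1 fell by 1.5 ± 0.16 (edgeR adjusted p = 0.00245). Klrg1, a receptor of terminally differentiated cells, rose by 5.64 ± 0.65 (edgeR adjusted p = 0.0028), Tbx21 by 2.32 ± 0.34, Il1rl1 by 1.99 ± 0.34 and Gata3 by 1.04 ± 0.23 (edgeR adjusted p = 0.0281). Maf rose by 1.46 ± 0.25 and Il10 by 1.80 ± 0.42 (edgeR adjusted p = 0.0311), while Foxp3 was at -0.22 ± 0.12 (edgeR adjusted p = 0.253) and Mki67 at 1.27 ± 0.38 (edgeR adjusted p = 0.0679).

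Of 19 naive and lymphoid homing genes, 0 rose and 16 fell (1 and 17 when adjusted over the list alone), with a median of -1.33 (camera adjusted p = 1.92e-49). Satb1 fell by 2.16 ± 0.10, with Bach2 at -2.22 ± 0.12, Id3 at -2.41 ± 0.14 and Lef1 at -1.55 ± 0.09. Of 12 thymocyte and recent emigrant genes, 0 rose and 6 fell (9 when adjusted over the list alone), with Sox4 at -2.95 ± 0.31 and Ldhb at -1.61 ± 0.17 (camera adjusted p = 8.446e-12). Of 16 GATA3 tissue Treg genes, 12 rose and 1 fell (13 and 1 when adjusted over the list alone), with Itgae up by 1.44 ± 0.09 and Gata1 down at -3.81 ± 0.30 (camera adjusted p = 6.406e-12). Of 17 suppressor effector genes, 11 rose and 1 fell (14 and 1 when adjusted over the list alone), with Fgl2 at 1.62 ± 0.17, Pdcd1 at 1.09 ± 0.15, Ctla4 at 1.07 ± 0.15 and Nt5e at 0.72 ± 0.08 (camera adjusted p = 2.406e-12). Of 10 Th2 genes, 6 rose and 0 fell (7 when adjusted over the list alone), with Il4 at 4.81 ± 0.41, Ccr8 at 1.22 ± 0.17 and Ccr4 at 1.32 ± 0.24 (camera adjusted p = 1.119e-07). These 5 calls held with an estimated correlation, with camera adjusted p from 0.0207 to 0.0452. They are not 5 separate results, since the GATA3 and Th2 lists share Gata3, Il1rl1, Ccr4 and Ccr8, among others.

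A further 7 lists were called by camera with the preset correlation but not with an estimated one. Of 10 thymic Treg-associated genes, 0 rose and 7 fell, as when adjusted over the list alone, with Swap70 at -3.65 ± 0.25 and Plagl1 at -4.92 ± 0.78 (camera adjusted p = 2.011e-10; adjusted p = 0.0854 with an estimated correlation). Of 17 intestinal Treg genes, 10 rose and 0 fell (14 when adjusted over the list alone), with Prdm1 at 1.61 ± 0.17, Ahr at 1.36 ± 0.16 and Icos at 1.37 ± 0.19 (camera adjusted p = 6.025e-14; adjusted p = 0.0854 with an estimated correlation). Of 14 gut homing genes, 6 rose and 0 fell (8 and 1 when adjusted over the list alone), with Gpr15 at 3.11 ± 0.20, Ccr2 at 1.40 ± 0.22 and Cxcr6 at 2.00 ± 0.40 (camera adjusted p = 2.323e-09; adjusted p = 0.0854 with an estimated correlation). Of 14 Th17 genes, 4 rose, among them Rora with 1.13 ± 0.18 (8 when adjusted over the list alone; camera adjusted p = 6.548e-06; adjusted p = 0.146 with an estimated correlation). Of 15 Tfh genes, 7 rose and 1 fell (7 and 3 when adjusted over the list alone), with Tox2 at 1.74 ± 0.26 (camera adjusted p = 0.000126; adjusted p = 0.133 with an estimated correlation). Of 50 cell cycle genes, 18 rose and 0 fell (31 when adjusted over the list alone), with Mcm2 at 0.72 ± 0.10, Mcm5 at 0.98 ± 0.15 and Tk1, which overlaps Afmid, at 1.75 ± 0.22 (camera adjusted p = 1.929e-14; adjusted p = 0.146 with an estimated correlation). Of 20 glycolysis genes, 10 rose and 1 fell (11 and 1 when adjusted over the list alone), with Aldoa and Tpi1, which overlap Fam57b and Spsb2, at 0.93 ± 0.11 and 1.11 ± 0.17 (camera adjusted p = 0.00187; adjusted p = 0.153 with an estimated correlation).

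Interferon genes again changed in 0 of 31 cases by edgeR without a block for the column numbers (camera adjusted p = 0.573). Myeloid and dendritic genes rose in 1 of 15 cases (camera adjusted p = 0.566), beside the 34.0 CPM of H2-Aa in tdTomato-negative GFP library 3 and 0.132 CPM in library 4. The largest falls included Selp, with 0 counts against 1414 and at least 419-fold lower, and Pld4, at least 358-fold lower but with 25.6 CPM in tdTomato-negative GFP library 3 against 0.572 CPM in library 4. Selp overlaps a gene model, so its level is uncertain. Acvr1c, which overlaps another, lay at 9.11 and 20.8 CPM in unmarked and 0.0677 and 0.0537 CPM in marked GFP cells. Lad1 fell by 6.52 ± 0.94, with Arhgap20 at -6.35 ± 0.83, Arhgap20os at -5.93 ± 0.89, Zdhhc14 at -5.92 ± 0.89, Pla2g4f at -5.86 ± 1.21, Ptprf at -5.78 ± 0.82 and Cldn10 at -5.53 ± 0.59. The largest rises beside Klrg1, Il4 and Gpr15 were Nid2 with 4.05 ± 0.78, Rasl11a with 3.36 ± 0.72, the growth factor gene Csf1 with 3.06 ± 0.22, Hspa2 with 3.02 ± 0.63, the granzyme gene Gzmb with 2.98 ± 0.48, Il17rb, which overlaps Actr8, with 2.96 ± 0.57, and Ryk with 2.89 ± 0.43. The fold of 15 of the 56 named genes past the threshold moved by over 1.5 times with 1 GFP library left out. Without tdTomato-positive GFP library 3 and without library 4, Lad1 was at -14.72 and -5.58, Arhgap20 at -9.499 and -5.485, Arhgap20os at -8.821 and -5.08, Pla2g4f at -4.924 and -9.498, Zdhhc14 at -5.113 and -7.95 and Plagl1 at -4.083 and -7.126, and without library 3 Klrg1 was at 4.76, Gzmb at 2.142 and Hspa2 at 1.962. Without tdTomato-negative GFP library 3 and without library 4, Nid2 was at 5.973 and 3.214, Klrg1 at 6.792 and 4.967 and Pld4 at -7.668 and -13.16, without library 3 Cxcr6 was at 2.883 and Gzmb at 3.664, and without library 4 Pla2g4f was at -5.021, Il17rb at 3.598, Acvr1c at -7.194 and Selp at -11.78. Values with a population at or near 0 counts, as for Acvr1c, Pld4 and Selp, depend on the prior count and give no size.

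In total 873 genes rose and 895 fell (1768; 4058 at an unadjusted p under 0.05), against 1030 and 871 by limma-voom, 706 and 974 under library totals, 107 and 193 in a fit to these 4 libraries alone, 296 and 673 without tdTomato-positive GFP library 3 and 141 and 317 without tdTomato-negative GFP library 4. Which direction held more genes thus depended on the processing. A fit to these 4 libraries alone called 300 genes. The count was 458 without tdTomato-negative GFP library 4, 969 without tdTomato-positive GFP library 3, 1065 without either tdTomato-negative Thy1.1 library, and 956 and 952 without Thy1.1 libraries 1 and 2 of the tdTomato-positive cells. Of the 56 named genes, 41 kept their call with each of the 8 libraries left out. The others were Ikzf2, Il1rl1, Ccr4, Tbx21, Mcm5, Pla2g4f, Gzmb and Ryk, lost without tdTomato-negative GFP library 4, Cxcr6, lost without tdTomato-positive GFP library 3, Il17rb, lost without library 3 of either GFP population, and Hspa2, lost without either tdTomato-negative GFP library or tdTomato-positive GFP library 3. Il10 was lost without tdTomato-negative GFP library 4, tdTomato-positive GFP library 3 or either tdTomato-positive Thy1.1 library, and Rasl11a without those 4 or tdTomato-negative GFP library 3. Gata3 was lost without any Thy1.1 or tdTomato-negative GFP library and was at 0.5062 without tdTomato-positive GFP library 3, and Pld4 without any library but tdTomato-negative GFP library 4. Mki67 passed without either tdTomato-positive Thy1.1 library. Each of the 12 list calls held with any 1 library left out.

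**Figure D3:**
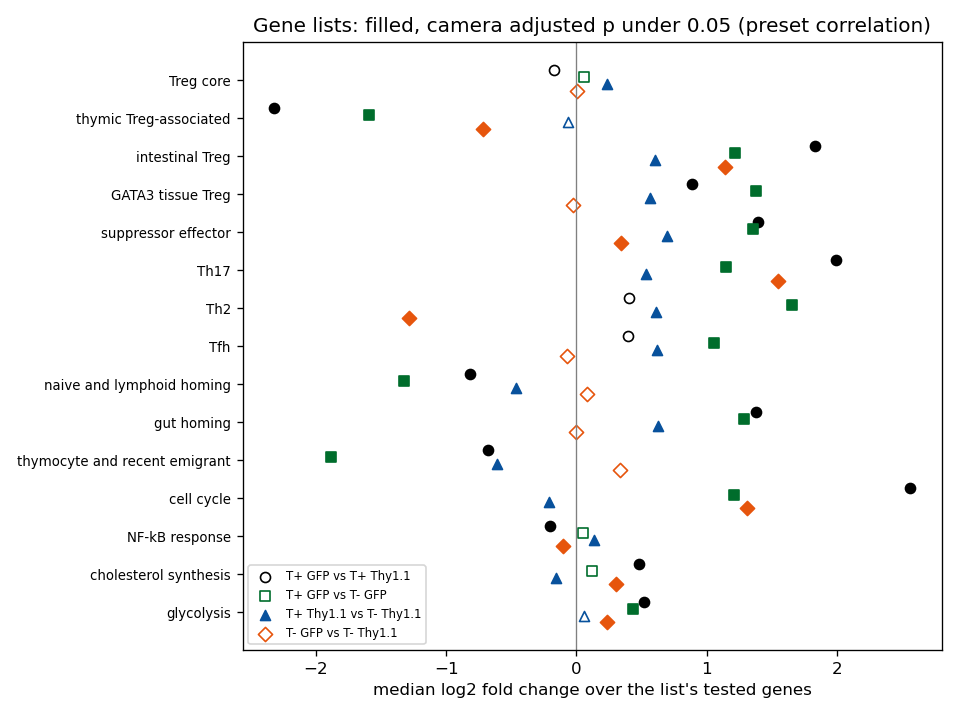
Median log2 fold change over the tested genes of each list called by camera in at least 1 of the 4 comparisons, with a marker per comparison, filled where the camera adjusted p was under 0.05 at the preset correlation. The naive and lymphoid homing list lay at -1.33 for the label in GFP cells and at -0.47 for the label in Thy1.1 cells.

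In Thy1.1 cells the same label was compared to ask whether marked cells of that reporter differed from unmarked ones. Gene by gene, edgeR called 0 of 13989 genes (1063 at an unadjusted p under 0.05), and it called 0 with each library left out. DESeq2 called 148, limma-voom 0 and a fit to these 4 libraries alone 2. Ccr7 was at -0.31 ± 0.12 (edgeR adjusted p = 0.632). Maf was at 1.17 ± 0.25 (edgeR adjusted p = 0.38), Il10 at 1.43 ± 0.42 (edgeR adjusted p = 0.545) and Tbx21 at 1.02 ± 0.33 (edgeR adjusted p = 0.58). Foxp3, Nrp1, Ikzf2, Il1rl1, Gata3 and Mki67 were at -0.01 ± 0.12, -0.02 ± 0.16, 0.25 ± 0.24, 0.12 ± 0.33, 0.47 ± 0.23 and 0.24 ± 0.38, each with an edgeR adjusted p of at least 0.712.

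Camera called 9 lists up and 4 down in Thy1.1 cells at the preset correlation, and 0 with an estimated correlation. Of 19 naive and lymphoid homing genes, 17 had a negative value, 11 fell when adjusted over the list alone, and the median was -0.47 (camera adjusted p = 9.151e-18; adjusted p = 0.0738 with an estimated correlation). The intestinal Treg list had a positive value for 16 of 17 genes, with 6 rising when adjusted over the list alone and a median of 0.60 (camera adjusted p = 8.496e-12; adjusted p = 0.137 with an estimated correlation). The suppressor effector list had a median of 0.69 and 8 genes that rose when adjusted over the list alone (camera adjusted p = 7.031e-11; adjusted p = 0.0855 with an estimated correlation). The Tfh, gut homing and GATA3 lists had medians of 0.62, 0.62 and 0.56 (camera adjusted p = 4.821e-09, 2.995e-07 and 1.308e-07; adjusted p = 0.0855, 0.137 and 0.0738 with an estimated correlation), and 6, 3 and 4 of their genes rose when adjusted over the list alone. The Th17, Th2 and Treg core lists were called up (camera adjusted p = 1.172e-06, 0.000907 and 0.000772; adjusted p = 0.138, 0.0891 and 0.0855 with an estimated correlation), with 0, 2 and 2 genes rising when adjusted over the list alone. Thymocyte genes were called down at a median of -0.61 (camera adjusted p = 0.000907; adjusted p = 0.138 with an estimated correlation), with 3 falling and 1 rising when adjusted over the list alone.

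The cell cycle list was called down in marked Thy1.1 cells, with 35 of 50 genes negative and a median of -0.21 (camera adjusted p = 0.000157; adjusted p = 0.465 with an estimated correlation). Its camera adjusted p was 0.0573 without tdTomato-positive Thy1.1 library 2. NF-kB response genes were called up (camera adjusted p = 0.0134; adjusted p = 0.19 with an estimated correlation), with a camera adjusted p of 0.115 without tdTomato-negative Thy1.1 library 1. Cholesterol synthesis genes were called down (camera adjusted p = 0.0106; adjusted p = 0.492 with an estimated correlation), with a camera adjusted p of 0.157 without that library and 0.286 without tdTomato-positive Thy1.1 library 2. The other 10 list calls held with any 1 library left out.

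The label effects of the reporters were set side by side from separate libraries. Of the 1768 genes called between marked and unmarked GFP cells, 1504 (85.1%) had the same sign in Thy1.1 cells, with a median ratio of the Thy1.1 to the GFP effect of 0.247. These genes were chosen by their GFP effect, which is also the divisor, so this ratio tends to be too low. Across all 13989 genes, which are not independent replicates, the effects correlated with r = 0.129 and a Spearman rho of 0.317, but r depended on the genes and libraries. It was 0.0682 with no filter, 0.41 with the stricter filter, 0.0727 and 0.0628 without tdTomato-negative Thy1.1 libraries 1 and 2, and 0.064 and 0.058 without tdTomato-positive GFP libraries 3 and 4. The interaction test called 62 genes, 13 with a more positive and 49 with a more negative label effect in GFP cells (1792 at an unadjusted p under 0.05). The difference of the label effect, GFP minus Thy1.1, was -1.47 ± 0.23 for Nrp1 (edgeR adjusted p = 0.0478). The other named interactions are given with the closing observations. Counts were 0 without tdTomato-negative Thy1.1 library 1 or 2 or tdTomato-positive Thy1.1 library 1, 1 without tdTomato-positive Thy1.1 library 2, 27 without tdTomato-negative GFP library 4 and 119 without tdTomato-positive GFP library 3. None of the named interaction calls, Nrp1 included, held with each library left out.

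The last comparison set unmarked GFP cells against unmarked Thy1.1 cells. Unmarked GFP cells had more of the inhibitory receptor genes Havcr2, which rose by 2.86 ± 0.29 (SE of log2, 2 libraries per population; edgeR adjusted p = 0.0148), and Lag3, by 1.86 ± 0.22 (edgeR adjusted p = 0.0329), and of the chemokine receptor gene Ccr2, by 2.23 ± 0.23 (edgeR adjusted p = 0.0148). Stom rose by 2.97 ± 0.28, Myb by 1.65 ± 0.22, Angptl2 by 1.41 ± 0.18 and Snx2 by 0.88 ± 0.11. Ebi3, a subunit gene of interleukin-35, fell by 2.64 ± 0.24 (edgeR adjusted p = 0.0146), as did Cd83 at -1.14 ± 0.11 and Thy1 at -1.01 ± 0.14 (edgeR adjusted p = 0.0481). The fall of Thy1, the gene of the sorted antigen, may follow from the sort. Boc fell by 3.98 ± 0.40, with Naip5 at -4.43 ± 0.56, Ttn at -3.03 ± 0.25, Susd2 at -2.98 ± 0.29, Abcb1a at -2.04 ± 0.15, Atp9a at -1.94 ± 0.25 and Pde2a at -1.39 ± 0.18. Slc7a10, chosen after its values were seen, had 0 counts against 829, at least 281-fold lower. Il1rl1 was at -2.40 ± 0.35 (edgeR adjusted p = 0.0525), Maf at 1.54 ± 0.25 (edgeR adjusted p = 0.0616), Nrp1 at -0.98 ± 0.16 (edgeR adjusted p = 0.0629) and Ikzf2 at -0.80 ± 0.24 (edgeR adjusted p = 0.239). Il10 and Mki67 were at 1.99 ± 0.43 and 1.45 ± 0.39, and Foxp3, Gata3, Tbx21 and Ccr7 at -0.27 ± 0.12, -0.05 ± 0.23, -0.34 ± 0.32 and 0.09 ± 0.12, each with an edgeR adjusted p of at least 0.125.

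By edgeR, 9 genes were higher and 14 lower (23; 1662 at an unadjusted p under 0.05), against 581 in total by DESeq2, 3 by limma-voom and 1 in a fit to these 4 libraries alone. Which direction held more genes depended on the processing, with 330 higher and 251 lower by DESeq2, 69 and 53 with the stricter filter, 58 and 40 with no filter and 59 and 16 without tdTomato-negative GFP library 4. Calls fell to 0 without any of the 4 Thy1.1 libraries and to 9 without tdTomato-negative GFP library 3, and rose to 75 without tdTomato-negative GFP library 4, 49 without tdTomato-positive GFP library 3 and 56 without tdTomato-positive GFP library 4. All 18 named genes past the threshold, including Havcr2, Lag3, Ccr2, Ebi3, Cd83 and Thy1, lost their call without each of the Thy1.1 libraries, and Maf passed without tdTomato-negative GFP library 4.

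Of 17 intestinal Treg genes, 2 rose and 0 fell between unmarked cells (12 rose when adjusted over the list alone), with a median of 1.14 (camera adjusted p = 1.733e-26; adjusted p = 0.154 with an estimated correlation). Of 50 cell cycle genes 0 passed over all genes, but 49 were positive and 32 rose when adjusted over the list alone, with a median of 1.31 (camera adjusted p = 7.078e-35; adjusted p = 0.154 with an estimated correlation). Of 10 thymic Treg-associated genes, 1 fell (4 when adjusted over the list alone), with a median of -0.72 (camera adjusted p = 5.222e-07; adjusted p = 0.154 with an estimated correlation). The Th17 list had a median of 1.55 with 7 genes rising when adjusted over the list alone (camera adjusted p = 1.328e-10; adjusted p = 0.154 with an estimated correlation), and the Th2 list a median of -1.29 with 1 rising and 2 falling when adjusted over the list alone (camera adjusted p = 0.00911; adjusted p = 0.16 with an estimated correlation). NF-kB response genes fell in 2 of 18 cases (3 when adjusted over the list alone; camera adjusted p = 0.000479; adjusted p = 0.154 with an estimated correlation), and cholesterol synthesis genes were called up with 0 passing (camera adjusted p = 0.000479; adjusted p = 0.393 with an estimated correlation). Suppressor effector genes rose in 2 and fell in 1 of 17 cases (7 and 3 when adjusted over the list alone; camera adjusted p = 0.00911; adjusted p = 0.393 with an estimated correlation), and the camera adjusted p was 0.0855 without tdTomato-negative Thy1.1 library 1 and 0.0959 without tdTomato-negative GFP library 3. Glycolysis genes were called up (camera adjusted p = 0.00911; adjusted p = 0.342 with an estimated correlation), with a camera adjusted p of 0.109 without tdTomato-negative GFP library 3. Naive and lymphoid homing genes were not called, with a median of 0.08 (camera adjusted p = 0.832), nor were GATA3 tissue Treg genes, at -0.02 (camera adjusted p = 0.939). These values stand beside 34.0 CPM of H2-Aa and 36.8 CPM of Siglech in tdTomato-negative GFP library 3.

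The reporter effects in marked and unmarked cells came from separate libraries. Of the 9 genes higher with GFP in unmarked cells, 9 were also called higher in marked cells, where independent lists would share 0.721. Of the 14 lower genes 12, Thy1 among them, were also called lower, where independent lists would share 0.955. Thy1 is the gene of the sorted antigen, so its fall in both comparisons may follow from the sort and is no separate result. Both tests used 1 model with a shared dispersion per gene, so the lists are not fully independent and these expected numbers are only a guide. GFP and Thy1.1 columns also share no number, and joint preparation was not tested. A difference of preparation between the reporters would enter both comparisons and could give such an overlap. Of the 2074 genes called in marked cells, 1813 (87.4%) had the same sign in unmarked cells, with a median ratio of 0.341. The genes were chosen by the effect in marked cells, which is also the divisor, so this ratio too tends to be low. Across all genes the effects correlated with r = 0.244 and a Spearman rho of 0.37. Here r was 0.148 with no filter, 0.589 with the stricter filter, 0.14 and 0.146 without tdTomato-negative Thy1.1 libraries 1 and 2, and 0.16 and 0.155 without tdTomato-positive GFP libraries 3 and 4.

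Interferon-response genes varied within every population by library number. The mean log2 CPM of the 31 tested list members was 5.52 and 6.99 in tdTomato-negative Thy1.1 libraries 1 and 2, 5.45 and 6.92 in tdTomato-positive Thy1.1 libraries 1 and 2, 5.37 and 7.13 in tdTomato-negative GFP libraries 3 and 4, and 4.70 and 6.82 in tdTomato-positive GFP libraries 3 and 4. Ifit3 lay between 6.61 and 16.5 CPM in odd-numbered and between 160 and 186 CPM in even-numbered libraries. Irf7, an inducer of the interferon response, lay between 69.5 and 81.4 CPM and between 248 and 282 CPM. Ifit3 and Irf7 were chosen as examples after their values were seen. Among libraries of like parity the mean was lowest in tdTomato-positive GFP cells. With odd and even column numbers as a block, chosen after the split was seen, edgeR called 7 of the 31 members between marked and unmarked GFP cells, 6 lower and 1 higher in marked cells (camera adjusted p = 0.0242; adjusted p = 0.516 with an estimated correlation), with Usp18 at -1.6 ± 0.34 (edgeR adjusted p = 0.0259). Between the reporters in tdTomato-positive cells calls in this fit included Ifit2 and Usp18, lower with GFP, and Zbp1, higher with GFP, genes named after their values were seen (camera adjusted p = 0.0759). For the interaction the list had a camera adjusted p of 0.0195 (adjusted p = 0.556 with an estimated correlation), and it was not called for the label in Thy1.1 cells or between the reporters in tdTomato-negative cells (camera adjusted p = 0.804 and 0.854). Leaving out libraries was not tested with this block.

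**Figure D4:**
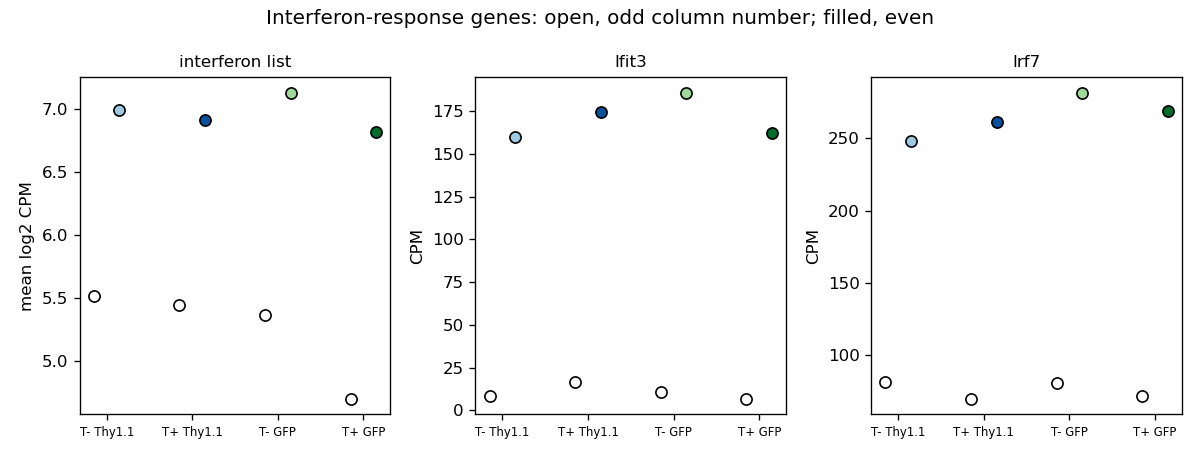
Mean log2 CPM of the 31 tested interferon-response genes and CPM of Ifit3 and Irf7 in each of the 8 libraries, by population, with open points for odd and filled points for even column numbers. Ifit3 lay at 160 to 186 CPM in the 4 even-numbered libraries and at 6.61 to 16.5 CPM in the 4 odd-numbered ones.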

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

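The tests of spread, depth and RNA of other cells in this part were chosen after the interaction had been seen. The tdTomato label had a different effect in GFP cells than in Thy1.1 cells for 62 genes by edgeR's interaction test, and values below are the log2 label effect in GFP minus that in Thy1.1 cells. Among naive and lymphoid homing genes the difference was -2.387 for Bcl2, -2.424 for Id3, -1.499 for Bach2, -1.132 for Lef1 and -2.499 for Treml2. It was -1.342 for Satb1, -1.858 for Ldhb and -1.633 for Cd1d1 among thymocyte genes, and -1.472 for Nrp1 and -3.395 for Swap70 among thymic Treg-associated genes. In the other direction it was 1.698 for Gpr15, 0.9762 for Itgae, 0.9558 for Mcm2, 3.795 for Kif23 and 2.698 for Uhrf1. Lef1 was named for the label in GFP cells and not by the rule for the interaction. Effects in GFP and Thy1.1 cells were -1.50 and -0.02 for Nrp1, and 3.11 and 1.41 for Gpr15. They were 1.439 and 0.4629 for Itgae, 0.7216 and -0.2342 for Mcm2, 1.022 and -2.773 for Kif23, and 1.482 and -1.217 for Uhrf1. The differences of Kif23 and Uhrf1 thus came in large part from negative values in Thy1.1 cells.

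Further genes with large differences were Gata1 at -3.231, Cecr6 at -3.354, Aldh2 at -2.734, Itm2a at -2.468 and Mctp1 at -2.439, and on the positive side Csf1 at 2.046, Ehd4 at 2.118, Sgk1 at 1.785, Abcb1a at 1.314, Arl5a at 1.224 and Prg4, which overlaps Tpr, at 1.177. The fitted differences of Selp (-11.32), Acvr1c (-7.637), Zc3h12c (-7.748) and Mcm10 (8.613) involve a population at or near 0 counts, depend on the prior count and give no size. Mcm10 lay at 5.21 and 2.90 CPM in tdTomato-negative and 0.0409 and 0 CPM in tdTomato-positive Thy1.1 cells, and at 13.8 and 6.80 CPM in tdTomato-negative and 27.5 and 20.7 CPM in tdTomato-positive GFP cells. All of the named calls were lost without at least 1 Thy1.1 library, with 0 genes called without tdTomato-negative Thy1.1 library 1 or 2 or tdTomato-positive Thy1.1 library 1, 1 without tdTomato-positive Thy1.1 library 2, 27 without tdTomato-negative GFP library 4 and 119 without tdTomato-positive GFP library 3.

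As lists, camera gave an interaction adjusted p of 1.128e-32 for naive and lymphoid homing genes, with a median difference of -1.02, 7 of 19 genes past the threshold and more negative in GFP cells and 15 when adjusted over the list alone, 6.534e-09 for thymocyte genes at -1.07 and 9.291e-15 for thymic Treg-associated genes at -1.51 (adjusted p = 0.0538 for each with an estimated correlation). It gave 5.712e-28 for cell cycle genes at 1.30 (adjusted p = 0.085 with an estimated correlation), 2.228e-06 for GATA3 tissue Treg genes at 0.70 and 4.104e-05 for Th2 genes at 1.71 (both adjusted p = 0.0538 with an estimated correlation). It gave 1.403e-05 for intestinal Treg, 4.064e-05 for suppressor effector, 0.0001175 for gut homing, 0.003429 for glycolysis and 0.005882 for cholesterol synthesis genes (adjusted p = 0.287, 0.169, 0.257, 0.257 and 0.476 with an estimated correlation). The cholesterol call alone was lost with a library left out, at a camera adjusted p of 0.0739 without tdTomato-positive Thy1.1 library 2 and 0.092 without tdTomato-positive GFP library 3. The other 10 held with any 1 library left out.

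The label called 1768 genes in GFP cells and 0 by edgeR in Thy1.1 cells (1063 at an unadjusted p under 0.05; DESeq2 148, limma-voom 0), and 3 technical explanations were weighed for the difference. Larger spread between Thy1.1 libraries is argued against by the biological coefficient of variation, 0.291 in the 4 Thy1.1 and 0.41 in the 4 GFP libraries. Both label tests, however, used 1 model of all 8 libraries with a common value of 0.399. The Thy1.1 label was thus judged against more than its own spread, which may have hidden calls. Fits to the 4 libraries of 1 reporter called 300 genes in GFP and 2 in Thy1.1 cells. With all libraries thinned to 1 total 70 genes had an interaction, so depth alone did not account for it. RNA of other cells in the GFP libraries numbered 3 is argued against as the whole cause by the GFP libraries numbered 4. Of 1099 genes called between marked and unmarked GFP cells without the latter, 94.2% had the same sign between the 2 libraries numbered 4, at a median ratio of 0.848, against 50.6% and 52.4% between libraries of 1 Thy1.1 population. These 1099 genes were called on 1 library per GFP population and serve only as a list to be read in the others. A label effect that depends on the reporter stays open as a biological hypothesis, which no test here decides. The design is a further limit, since the toxin receptor is named with the GFP reporter only and toxin was given during marking. Toxin may have acted unequally on the marked and unmarked cells of the 2 reporters, and no comparison here can separate this from the label. Whether GFP and Thy1.1 libraries were prepared together was not tested.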

How the results depend on the processing

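The fits with odd and even column numbers as a block, without both GFP libraries numbered 3 and on thinned counts were chosen after the data were seen. Counts below follow the order GFP against Thy1.1 in tdTomato-positive cells, label in GFP cells, label in Thy1.1 cells, GFP against Thy1.1 in tdTomato-negative cells and interaction. DESeq2 called 3164, 2974, 148, 581 and 568 genes against 2074, 1768, 0, 23 and 62 by edgeR. For the last 2 comparisons limma-voom called 3 and 36, no filter 98 and 109, and the stricter filter 122 and 133. A fit to 2 populations alone called 300, 2 and 1 for the label in GFP cells, the label in Thy1.1 cells and the reporters in tdTomato-negative cells. The odd and even block gave 39 and thinning 38 in tdTomato-negative cells. Without both GFP libraries numbered 3, which leaves 1 library per GFP population, 2 genes were called for the label in Thy1.1 cells, 210 for the interaction, and the relation of the reporter effects had r = 0.193. For these counts the cause was not tested, except that a fit to fewer libraries has fewer degrees of freedom. The estimated correlation left 0, 5, 0, 0 and 0 list calls, and fry called 6 lists for the label in Thy1.1 cells and 2 for the reporters in tdTomato-negative cells. The relations of label and of reporter effects had r = 0.0682 and 0.148 with no filter and 0.41 and 0.589 with the stricter filter, which removes low-count genes.

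With each library left out, the lone library of a population was assumed to vary like the others. Gene counts then ranged from 481 to 2118, from 458 to 1801, from 0 to 0, from 0 to 75 and from 0 to 119, list calls from 12 to 18, 12 to 14, 12 to 15, 9 to 12 and 10 to 14, and the relations from 0.058 to 0.135 and from 0.14 to 0.225. A replicate block gave 2039 genes for the label in GFP cells, of which 1575 were among the 1768, and 0 in Thy1.1 cells. It gave 78 for the interaction, of which 42 were among the 62. With odd and even numbers as a block, 46 of the 62 were still called. Among named genes, 9 calls were lost with the replicate block and 8 with the odd and even block. Deviations of same-numbered libraries correlated at 0.056 in GFP and 0.0509 in Thy1.1 cells over all genes, while interferon genes split by number. GFP and Thy1.1 columns share no number, and for the reporter comparisons odd and even numbers as a block gave 2214 genes in tdTomato-positive and 39 in tdTomato-negative cells. Named genes kept their side of the threshold in 3043 gene and setting pairs, gained a call in 37 and lost one in 442. A change of sign was counted only where the gene was called in at least 1 of the 2 fits, and there were 0. Signs of genes called in neither fit could change within the 3043 pairs. The odd and even block also gave calls among interferon genes for the label in GFP cells. Counts under RLE factors and library totals stayed within 1.5 times the reported ones, although the direction with more genes turned for the reporters in tdTomato-positive cells under library totals. Depth limits genes near 3 counts, and between 14943 and 15863 genes had a count.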

Other observations

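The gene families in this part, the depth test of the interferon genes, the test of myeloid RNA, the test of a fixed share of marked-type cells and the way the shared-source and X chromosome tests are read were chosen after the results were seen. Families were taken by gene symbol, and each median given here kept its sign under TMM, RLE factors and library totals. In tdTomato-positive cells, 21 of 38 proteasome subunit genes were higher with GFP than with Thy1.1 and 0 lower, with a median log2 fold change of 0.46 (camera adjusted p = 1.54e-08 over the families; adjusted p = 0.264 with an estimated correlation). Mitochondrial ribosomal protein genes rose in 13 of 74 cases and fell in 0 (camera adjusted p = 2.7e-05; adjusted p = 0.501 with an estimated correlation), whereas 1 of 82 cytosolic ribosomal protein genes rose and 1 fell (camera adjusted p = 0.955). All but 2 of 9 genes with a minichromosome maintenance symbol, several of which license replication, rose, with a median of 1.27 (camera adjusted p = 1.18e-13; adjusted p = 0.0382 with an estimated correlation). This family shares genes with the cell cycle list.

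Chemokine receptor genes rose in 8 of 18 cases and fell in 1 in that comparison, with a median of 1.41 (camera adjusted p = 1.39e-05; adjusted p = 0.121 with an estimated correlation), Ccr1, Ccr3, Ccr6 and Ccr9 among those that rose. The fall was in Ccr7. Of 7 S100 calcium-binding protein genes, 5 rose, among them S100a4, S100a6, S100a10 and S100a11 (camera adjusted p = 2.62e-06; adjusted p = 0.264 with an estimated correlation). Of 9 annexin genes, 4 rose (camera adjusted p = 0.00544; adjusted p = 0.264 with an estimated correlation). Of 10 MHC class I genes, 4 fell, including H2-K1 and H2-M3, at a median of -0.56 (camera adjusted p = 0.00585; adjusted p = 0.501 with an estimated correlation). Reads of these near-identical genes cannot be assigned safely to 1 copy.

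Unmarked GFP cells lay between unmarked Thy1.1 and marked GFP cells for several lists, so that a fixed share of marked-type cells among them is a candidate explanation. The genes used were those called between the reporters in tdTomato-positive cells, with a mean of at least 5 CPM. Per gene, the gap from unmarked Thy1.1 to unmarked GFP cells was divided by that from unmarked Thy1.1 to marked GFP cells. Marked GFP cells thus took part both in choosing the genes and in the divisor. The median share was 26.3% for the intestinal Treg list (14% to 41.1% over 8 choices of 1 library per population), 29.7% for cell cycle genes (15.9% to 47.6%), 25.4% for Th17 genes (12.5% to 47%), 23.3% for GATA3 tissue Treg genes (13.8% to 38.6%), 47.1% for thymic Treg-associated genes (21.7% to 63.8%) and -10.6% for naive and lymphoid homing genes (-21.1% to 4.79%). The naive list thus argues against 1 share for all 6 lists, while the ranges of the other 5 overlap. Some of these lists, such as Th17 and intestinal Treg, share genes, so their shares are not separate results. These shares rest on called genes only, and over all 16 tested GATA3 tissue Treg genes unmarked GFP cells had a median of -0.02 against unmarked Thy1.1 cells, with 7 positive and 9 negative, so 1 share for the 5 lists is not shown. For the intestinal Treg list, RNA of other cells in tdTomato-negative GFP library 3 is argued against as the whole cause. Its median against unmarked Thy1.1 cells was 0.886 without that library and 1.14 with it. This does not extend to every list, since the suppressor effector and glycolysis calls between unmarked cells were lost without that library. Other mixtures, and a state of these cells between the other populations, stay open. Toxin may also have acted on unmarked GFP cells and not on the unmarked Thy1.1 cells used as the baseline, which was not tested.

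Interferon-response genes split by column number, with 30 of 31 list members higher in the even-numbered library in all 4 populations and a mean of 1.71 on the log2 scale (3.26-fold), from 2.77-fold in tdTomato-positive Thy1.1 cells to 4.35-fold in tdTomato-positive GFP cells. The difference was 1.71 after thinning to 1 total, but totals were so alike that thinning could hardly move it. The tdTomato-negative GFP libraries 3 and 4 had 45764437 and 46007968 counts and still differed 3.4-fold, which argues against depth. The interferon list summed to 2729 to 3160 CPM more in the even-numbered library of a population, whereas the 15 tested myeloid and dendritic genes summed to at most 20.8 CPM more, in tdTomato-positive Thy1.1 cells, and to less in the other populations, which argues against RNA of those cells. Animals, a day or a preparation shared across the 4 populations may be the source, which these calls cannot decide. Here edgeR called 65 genes, all higher in even-numbered libraries, 23 from the list and 42 outside it. Many of the 42, such as Gbp10, Ifit3b, Cmpk2, Iigp1, Ifitm3 and Oas3, are also interferon-response genes, so they repeat the split to be explained. Without the list, deviations of odd-numbered libraries from their population mean correlated between populations at only 0.0243 to 0.0476. Of the 8 within-population splits of the libraries, 1 gave as many genes, the real one with 65 against at most 0 in the others, and 8 splits are too few for a share under 0.05.

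Foxp3 lies on the X chromosome, so cells sorted by the 2 reporter alleles might also differ in other X-linked genes. Of 455 tested X-linked genes, 14.1% were called between the reporters in tdTomato-positive cells, against 15% of other genes (odds ratio 0.929, 95% interval 0.699 to 1.22, two-sided Fisher's exact test p = 0.64). A higher rate on the X chromosome was not detected, and the interval leaves small differences in either direction open.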
